A study of Mus musculus with 4 samples.

How the data were processed

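Gene expression was measured in the livers of male C57BL/6J mice on 4 single-colour Affymetrix arrays. The mice were 8 to 12 weeks old at the start and received a low-fat diet with 10% of energy from fat, or a high-fat diet with 45% of energy from fat, for 20 weeks. In the last week they were injected into the peritoneal cavity with liposomes holding clodronate, which kill phagocytes that take them up, or with phosphate-buffered saline (PBS). Per the labels' protocols, equal amounts of liver RNA from each animal of a group were pooled, and each pool was hybridised to 1 array from 5 µg of total RNA with an RNA integrity number above 8.0. The pools held RNA from 8 mice per group on the low-fat diet and from 10 mice per group on the high-fat diet, 36 mice in all. A group was therefore 1 array, and the spread between mice was not measured. For arrays it can only be said that their number, 1 per group, limits the precision.

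The deposited table held log2 expression values of 45101 probe sets, which the authors made with GCRMA 2.24.1, per the submitters' processing notes. GCRMA corrects each probe for background with a model of its sequence, brings the arrays to 1 distribution and summarises probes into probe sets. The values were used as deposited, and no scanner files were used here. The medians of the 4 arrays over all probe sets lay between 2.73 and 2.79 (log2), and the share of probe sets at 4 or more between 33.5% and 34.5%. Pearson's r between arrays over all probe sets, which are not independent replicates, lay between 0.994 and 0.996. Values below 4 were treated as too dim to measure, so that a difference against such a value is a bound, written as "at least".

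Probe sets were named through the platform annotation supplied with the table. It listed 35890 probe sets, of which 34958 carried 1 gene symbol and 932 several, and 9211 probe sets of the table had no symbol. Entrez identifiers of 34754 probe sets were found in the mouse RefSeq gene table of assembly GRCm38.p6, which was used only for names and changed 0 symbols. No genomic coordinates were used. Each of the 18194 genes was represented by the probe set with the highest mean over the 4 arrays among probe sets with 1 symbol, and 9012 genes had several such probe sets. The 8650 genes at 4 or more on at least 1 array were analysed. Some genes of the fixed lists had no probe set with a single symbol and are not analysed here.

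The main settings, the gene lists, the alternatives and the rule for named genes were chosen before the data were examined. For each pair of arrays the log2 difference per gene was taken after values below 4 had been set to 4, and genes differing 2-fold or more were counted. These differences have no replicate check, and no p-value was computed for them. For each of 32 gene lists, 14 of cell type markers and 18 of pathways, the median difference was set against 10000 random lists of the same size whose members were drawn from the 200 genes nearest in mean expression. The percentile is given for the 23 lists with at least 3 detected members and only describes these arrays. Members that were below 4 on both arrays of a pair entered the median as 0. The effects of clodronate and of diet, each averaged over the other factor, were tested with limma 3.58.1 in R 4.3.3 in an additive model on all 4 arrays, with a mean-dependent prior variance in eBayes and Benjamini-Hochberg adjustment at 0.05 over the 8650 genes. The values below 4 were left as deposited in this model. It has 1 residual degree of freedom per gene, which holds noise and any difference of the clodronate effect between the diets together, and a prior of 8.46 degrees of freedom taken from all genes. The p-values measure only the spread between these arrays, which may be technical, and not the spread between mice. Counts per list were made over all genes and adjusted over the list alone. The remaining steps used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

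The additive model was tested on simulated data with 200 changed genes among 8650 in each of 20 runs. It recovered 83.9% of genes changed 2-fold and 100% of genes changed 4-fold, and 13.5% of its calls were unchanged genes, more than the nominal 5%. Without the mean-dependent prior it recovered 41.2% and 96.4%, and 2.67% of its calls were unchanged genes. The percentile of lists placed 9 of 200 unchanged random lists outside the central 95%, and the upper tail held 200 of 200 lists shifted by 0.3 on the log2 scale. These lists held random genes with permuted differences, so they do not cover lists whose genes vary together.

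Named genes were taken by a fixed rule. For each pair of arrays these were the 6 genes with the largest difference per direction among genes at 4 or more on both arrays, up to 3 per direction with the largest bound, and up to 4 members per list with the largest difference. For the averaged effects they were the 6 genes per direction with the largest mean difference among those past the threshold, on values as deposited, so that the order of genes with an array below 4 means little. A further set of genes of fatty acid oxidation, lipid synthesis, cytokines and Kupffer cells was always taken where a probe set with a single symbol existed, and predicted genes could be passed over. Where a named gene differed 2-fold or more and had other detected probe sets, they differed in the same direction for 12 of 13 in the clodronate comparison on the low-fat diet, 11 of 13 on the high-fat diet, 11 of 13 in the diet comparison with PBS and 24 of 24 with clodronate. The exceptions were probe sets of Tfpt, Zfp62, Adgre4, Steap2 and Tpm2. Over differences of any size, 22, 28, 27 and 15 of 108 other probe sets had the opposite direction in the comparisons in this order.

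Alternatives changed 1 choice at a time, except that the floor and the filter on dim genes changed together. They were the mean over all probe sets of a gene, floors of 3 and 5, no floor and no filter, centring of each array on its median, quantile normalization of the 4 arrays, thresholds of 1.5-fold and 3-fold, eBayes without the mean-dependent prior, genes at 6 or more only, and random lists not matched on expression. Setting values below 4 to 4 before the additive fit was added after the data were seen.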

Results

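Liver expression was measured in 4 pools of mice that differed in diet and in whether clodronate liposomes, which deplete macrophages, or PBS had been injected. With PBS as the control, effects of the liposomes, of clodronate and of macrophage loss cannot be told apart. The groups were low-fat diet with PBS, low-fat diet with clodronate, high-fat diet with PBS and high-fat diet with clodronate, with 1 pooled array each. Of 45101 probe sets, 15405, 15562, 15346 and 15131 were at 4 or more on the arrays of these groups in this order. The question was what Kupffer cells, the resident macrophages of the liver, do to liver fat, and whether interleukin-1β and PPARα, a nuclear receptor of fatty acid oxidation, take part. No group had a replicate array, so the differences between single arrays have no replicate check, and only effects averaged over the other factor were tested.

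On the low-fat diet, the signal of Kupffer cell genes was far lower after clodronate. Clec4f, a C-type lectin receptor of Kupffer cells, was at 9.40 (log2) with PBS and 1.92 with clodronate, at least 42.3-fold lower. Vsig4, a complement receptor, was at least 60.1-fold lower, and Cd5l, a secreted macrophage protein, at least 105-fold lower, from 10.71 to 3.38. C1qb, a chain of complement C1q, was 56.4-fold lower, and Csf1r, the receptor for macrophage colony-stimulating factor, 20.3-fold lower. The largest measured differences also included Cd44, Ctss, Cybb and Tyrobp, which were between 6.04-fold and 7.76-fold lower.

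With values below 4 taken as 4, which bounds the difference of dim markers such as Folr2, the median difference of the 12 Kupffer cell markers on the low-fat diet was -1.77, under all 10000 matched random lists, and 9 of the 12 were 2-fold or more lower. The median of the 13 pan-macrophage markers was -1.86, and 10 of them were 2-fold or more lower. C6, named after its value was seen, is listed as a Kupffer cell marker but also made by hepatocytes, and differed by -0.10. The lists of sinusoidal endothelial cells with 14 detected members, stellate cells and matrix with 11, and hepatocytes with 12 had medians of 0.09, 0.09 and -0.01, at percentiles 82.0, 80.0 and 10.5 of random lists. Stab2, an endothelial scavenger receptor, differed by 0.03, and the endothelial list ranged from -0.44 for Cdh5 to 0.25 for Lyve1.

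Few genes were higher after clodronate on the low-fat diet. Lcn2, an acute phase protein that binds bacterial iron carriers, was 6.69-fold higher, from 4.94 to 7.68. Mt1, a metallothionein, was 2.98-fold higher and Anxa1, annexin A1, 2.43-fold higher. Cish and Socs2, feedback inhibitors of cytokine and growth hormone signalling, were 3.30-fold and 2.13-fold higher, and Rgs3 was 2.62-fold higher. Another Rgs3 probe set differed by only 0.37 (log2). Cyp26a1, which degrades retinoic acid, was at least 4.63-fold higher, and Pdzrn3 and Pla2g12a at least 1.72-fold and 1.99-fold. Tfpt was 2.44-fold higher by the probe set used, but other probe sets of this gene were not all in the same direction. In all, 19 of 8650 genes were 2-fold or more higher and 61 were 2-fold or more lower, 25 of the latter as bounds.

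**Figure D1:**
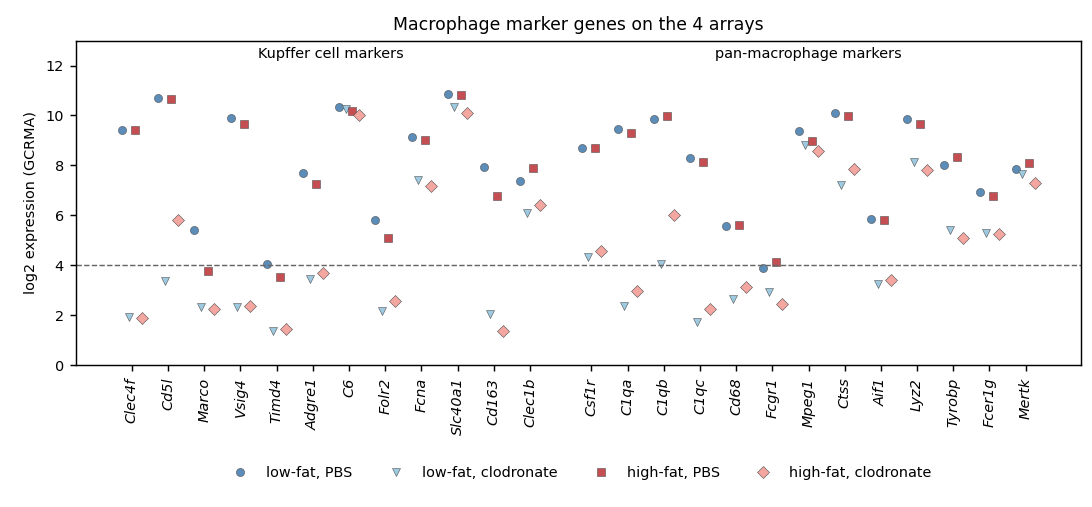
GCRMA log2 expression (vertical axis) of 12 Kupffer cell and 13 pan-macrophage marker genes (horizontal axis), with 1 point per pooled array and the dashed line at 4. Clodronate points lie far below PBS points for Clec4f (9.40 against 1.92 on the low-fat diet), whereas those of C6 lie close together, and Cd5l and C1qb stayed at 5.82 and 6.02 in the high-fat clodronate pool.

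On the high-fat diet, macrophage transcripts were also far lower after clodronate. Clec4f was at 9.42 with PBS and 1.88 with clodronate, at least 42.9-fold lower, Vsig4 at least 50.7-fold lower and C1qa at least 38.8-fold lower. Cd5l was 28.2-fold lower, Csf1r 17.2-fold lower and C1qb 15.4-fold lower. Tyrobp, Cfp and Adgre4 were 9.31-fold, 7.39-fold and 7.14-fold lower. The Kupffer cell list had a median of -1.67, with 8 of 12 members 2-fold or more lower, and the pan-macrophage list a median of -1.87, with 10 of 13. Marco, a scavenger receptor, was already at 3.77 in the high-fat PBS pool, so that no difference from the clodronate pool could be measured. Medians of the sinusoidal endothelial, stellate and hepatocyte lists were 0.03, -0.02 and -0.04, at percentiles 95.8, 70.0 and 42.5. The endothelial list ranged from -0.75 for Pecam1 to 0.64 for Lyve1, with Cdh5 at -0.39.

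Orm2, an acute phase glycoprotein, was 7.63-fold higher after clodronate on the high-fat diet, from 7.15 to 10.08. Pik3cd was 5.12-fold, Rexo5 2.47-fold, Zfp62 2.14-fold and Anp32a 2.13-fold higher, and Sema3f at least 2.93-fold. Other probe sets of Zfp62 did not all share its direction, and those of Anp32a differed by only 0.09 and 0.25 (log2). Pik3cd was at 4.05 with PBS, close to the floor of 4. Ighm, an immunoglobulin heavy chain gene, was 2.02-fold higher, and Igkv8-30, another immunoglobulin gene, was higher by 1.03 (log2). Csdc2 and Slc22a29 were at least 1.97-fold and 1.75-fold higher. In all, 8 of 8650 genes were 2-fold or more higher and 70 were 2-fold or more lower.

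The genes with lower signal were largely shared by the diets, and those with higher signal were not. Of the 61 and 70 genes that were 2-fold or more lower, 52 were lower on both diets, where 0.494 would be shared by independent lists. Of the 19 and 8 genes that were higher, 1 was shared, Orm2, where 0.0176 would be shared by independent lists. The comparisons have no array in common. Across the 8650 genes, which are not independent replicates, Pearson's r was 0.464 and Spearman's rho -0.0299.

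**Figure D2:**
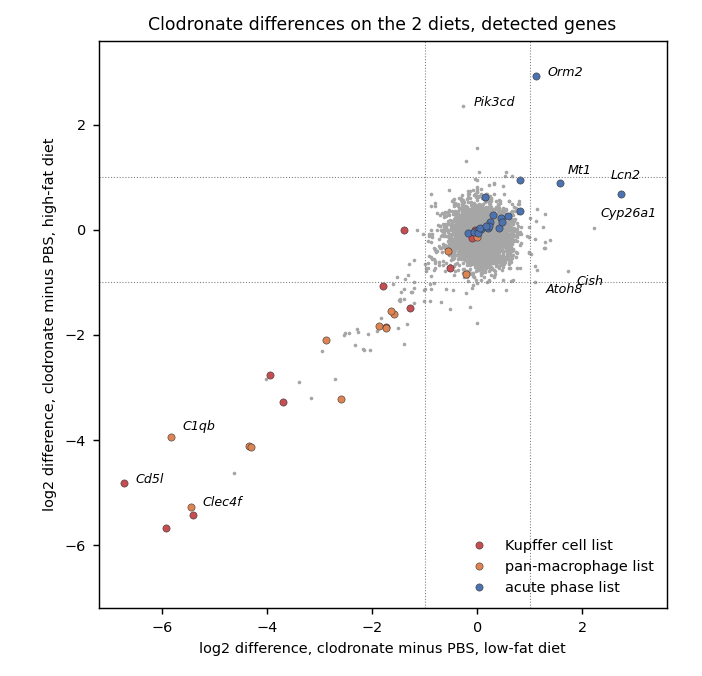
Log2 difference between clodronate and PBS on the low-fat diet (horizontal axis) and on the high-fat diet (vertical axis) for 8650 detected genes, with members of 3 gene lists coloured and dotted lines at 2-fold. The Kupffer cell and pan-macrophage genes form a tail toward the lower left, down to -6.71 for Cd5l on the low-fat diet, while Lcn2 (2.74 and 0.69) and Orm2 (1.12 and 2.93) stand out to the right and above.

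Averaged over both diets, 84 genes fell and 10 rose after clodronate (limma with Benjamini-Hochberg adjustment). With values below 4 taken as 4, 92 of the 94 differed in the same direction on both diets, and Marco and Timd4 had no measurable difference on the high-fat diet. Among the 12 Kupffer cell markers 11 fell, all but C6, and 11 also fell adjusted over the list alone. The calls of Timd4, at most at 4.04 on any array, and of Marco, below 4 on 3 of 4 arrays, rest on values below 4. Of the 13 pan-macrophage markers 10 fell, and 13 fell adjusted over the list alone. Csf1r, measured on all 4 arrays, fell by 4.22 ± 0.17 (SD of the differences on the 2 diets, n = 2; limma with Benjamini-Hochberg adjustment, adjusted p = 5.94e-07). Lyz2, lysozyme of myeloid cells, fell by 1.80 ± 0.09 (limma, Benjamini-Hochberg adjusted p = 1.3e-05). Fcna, a ficolin of Kupffer cells, fell by 1.80 ± 0.08 (limma, Benjamini-Hochberg adjusted p = 3.16e-05). Clec4f, Vsig4, C1qa, C1qc, Cd5l and Cd163 also fell, but were below 4 after clodronate on both diets, or for Cd5l on the low-fat diet, so that bounds are given. C1qc was at least 19.7-fold and 17.5-fold lower, and Cd163, the haemoglobin scavenger receptor, at least 15.5-fold and 6.82-fold lower. Of the 14 endothelial, 11 stellate and 12 hepatocyte markers, 0 were called in limma, and 0 adjusted over each list alone.

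Hmox1, haem oxygenase 1, fell by 2.03 ± 0.07 (limma, Benjamini-Hochberg adjusted p = 0.000404) and Slc11a1, a metal transporter of phagosomes, by 2.11 ± 0.23 (limma, Benjamini-Hochberg adjusted p = 0.000404). These were 2 of 11 detected members of the iron list over all genes and adjusted over the list alone. The list had a median of 0.19 with 8 members above 0 on the low-fat diet, and a median of -0.19 with 3 members above 0 on the high-fat diet, both outside the central 95% of random lists. Slc40a1, the iron exporter ferroportin and a member of the Kupffer cell list, fell by 0.62 ± 0.16 (limma, Benjamini-Hochberg adjusted p = 0.0053).

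Acute phase genes, most of which encode proteins that hepatocytes secrete in inflammation, rose after clodronate. Of 21 members 6 rose, and 10 rose adjusted over the list alone, with list medians of 0.24 on the low-fat and 0.14 on the high-fat diet, above all 10000 random lists in each. Saa1, serum amyloid A1, rose by 0.88 ± 0.10 (limma, Benjamini-Hochberg adjusted p = 0.000198). Orm2 rose by 2.03 ± 1.28 (limma, Benjamini-Hochberg adjusted p = 0.0129), Mt1 by 1.23 ± 0.49 (limma, Benjamini-Hochberg adjusted p = 0.00928) and Lbp, which binds lipopolysaccharide, by 0.59 ± 0.32 (limma, Benjamini-Hochberg adjusted p = 0.0391). The other members that rose were Orm1 and Hp, haptoglobin, by 0.29 and 0.34. Lcn2 did not pass (mean difference 1.71 ± 1.45; limma, Benjamini-Hochberg adjusted p = 0.0842). Outside the list, Gpcpd1 and Tmem176a rose by 0.68 ± 0.17 and 0.53 ± 0.25, although a dim probe set of Gpcpd1 was lower by 0.49 on the high-fat diet.

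Most genes of the endoplasmic reticulum stress response were lower after clodronate, with 9 of 12 detected members below 0 on each diet. Chac1, which degrades glutathione, was higher on both diets, by 0.52 and 0.38, without passing. The median of the members was -0.34 on the low-fat diet, under all random lists, and -0.16 on the high-fat diet, at percentile 1.16. Creld2, an endoplasmic reticulum chaperone partner, fell by 0.71 ± 0.29 (limma, Benjamini-Hochberg adjusted p = 0.00928) as the single member called over all genes, and 5 fell adjusted over the list alone. Interferon response genes had a median of -0.28 on the low-fat diet, under all random lists, and -0.22 on the high-fat diet, at percentile 3.25, inside the central 95%. Of 14 members Cxcl9, a chemokine, fell (mean difference -1.21 ± 0.45; limma, Benjamini-Hochberg adjusted p = 0.00594), and 2 fell adjusted over the list alone.

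PPARα target genes were close to 0 after clodronate. The median of 26 detected members was 0.05 on the low-fat diet, at percentile 78.1, and -0.03 on the high-fat diet, at percentile 72.2, and 0 members were called in limma over all genes or adjusted over the list alone. Cpt1a, which admits fatty acids into mitochondria, differed by 0.16 and 0.06 on the low-fat and high-fat diets, and Cyp4a14, a fatty acid hydroxylase, by -0.09 and -0.48. Ppara itself differed by 0.08 and 0.09, Pdk4 by -0.38 and 0.20, and Fgf21 by -0.55 on the low-fat diet. Lipogenesis genes had medians of -0.01 and -0.03 with 0 of 18 called. The cytokine genes Il1b, Il1rn and Tnf were below 4 on all 4 arrays, at most at 3.48, 3.33 and 2.81, so a difference in them was not measurable. Of the 7 detected members of the interleukin-1 and NF-κB list 0 were called over all genes and 1 rose adjusted over the list alone, with medians of 0.02 and 0.05. On each diet 5 members were above 0 and 2 below. The largest rise was that of Cxcl1, by 0.49 on the low-fat and 0.84 on the high-fat diet.

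The calls for clodronate depended on how the variance was modelled. With eBayes without the mean-dependent prior 39 genes fell and 0 rose, with 441 genes at an unadjusted p under 0.05 against 410 in the main model, and 6 Kupffer cell, 8 pan-macrophage and 0 acute phase members were called. Of the 94 genes called, 42 were below 4 on at least 1 array. In simulated data 13.5% of the calls of the main model were unchanged genes.

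In PBS-injected mice, genes of fatty acid synthesis were lower on the high-fat diet. Acacb and Acaca, the acetyl-CoA carboxylases, were 2.71-fold and 2.13-fold lower, Elovl6, a fatty acid elongase, 2.30-fold lower and Fasn, fatty acid synthase, 1.70-fold lower. Pnpla3, a lipase of lipid droplets, was at least 2.19-fold lower. The median of the 18 lipogenesis genes was -0.50, under all random lists. Fabp5, a fatty acid binding protein, was 5.95-fold lower, Acpp 4.78-fold, Mmd2 3.13-fold, Igfbp1, an insulin-repressed binding protein, 2.77-fold and Qtrt2 2.62-fold lower. Lepr, the leptin receptor, was at least 4.91-fold lower, Marco at least 2.63-fold and Tff3 at least 2.40-fold.

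Several genes of lipid storage, fatty acid oxidation and xenobiotic metabolism were higher on the high-fat diet with PBS. Fitm1, which helps to form lipid droplets, was 2.74-fold higher and Cd36, a fatty acid transporter, 1.66-fold. Cyp4a14 and Vnn1, PPARα targets, were 2.20-fold and 2.18-fold higher, and the 26 PPARα targets had a median of 0.24, above all random lists. The PPARα targets Pdk4 and Fgf21 were lower instead, by 2.37-fold and at least 2.20-fold, so that 2 members were 2-fold or more higher and 2 lower. Cyp2b9 and Cyp2b10, cytochromes P450, were at least 6.23-fold and 3.42-fold higher. Cyp2b10 was above 4 only in the high-fat PBS pool. With clodronate it had no measurable diet difference, and on the high-fat diet it was at least 3.42-fold lower after clodronate. The xenobiotic list had a median of 0.14 with diet under PBS, but of -0.11 after clodronate on the high-fat diet, at percentile 0.37. Both values use the high-fat PBS array. Tpm2, a tropomyosin, was 3.96-fold, Usp2 3.93-fold, Lcn2 3.86-fold, Dbp, a clock output factor, 2.68-fold and Slc46a3 2.67-fold higher. Pdzrn3 was at least 2.35-fold higher. The Kupffer cell list was slightly lower, with a median of -0.13 at percentile 1.45, and Cd163 was 2.27-fold lower. In all, 29 genes were 2-fold or more higher and 29 were 2-fold or more lower.

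In clodronate-injected mice the lipogenesis genes were lower on the high-fat diet too, with a median of -0.38, under all random lists. Elovl6 was 2.40-fold lower, Acacb 2.21-fold, Acaca and Me1 2.05-fold and Fabp5 3.94-fold lower. The PPARα targets had a median of 0.16, above all random lists. Lepr, Steap2 and Tff3 were at least 7.11-fold, 3.75-fold and 3.35-fold lower. Rgs3 was 5.33-fold, Cish 5.14-fold, Cyp26a1 4.52-fold, Socs2 4.47-fold and Serpina4-ps1 4.36-fold lower. Another Rgs3 probe set differed by only -0.55 (log2). With PBS, Rgs3, Cish, Socs2 and Serpina4-ps1 had differences of -0.83, 0.14, -0.38 and -0.50 (log2), and Cyp26a1 was below 4 on both diets. Whether these differed between the injections was not tested. Glucose metabolism genes had a median of -0.27, under all random lists, and endoplasmic reticulum stress genes of 0.17, at percentile 99.9, while with PBS both medians were -0.02.

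Usp2 was 8.29-fold higher on the high-fat diet with clodronate, Tpm2 4.46-fold, Orm2 3.06-fold, Egr1, an immediate early factor, 2.99-fold and Per3, a clock gene, 2.87-fold. The macrophage genes C1qb and Cd5l were 3.93-fold and at least 3.54-fold higher, Cyp2b9 at least 3.72-fold and Pik3cd at least 5.32-fold. The Kupffer cell and pan-macrophage lists each had a median of 0 in this comparison, in which members below 4 on both arrays entered as 0. In all, 31 genes were 2-fold or more higher and 64 were 2-fold or more lower. The split between directions moved with the scaling, to 40 higher and 41 lower after centring of each array and to 43 higher and 40 lower after quantile normalization.

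**Figure D3:**
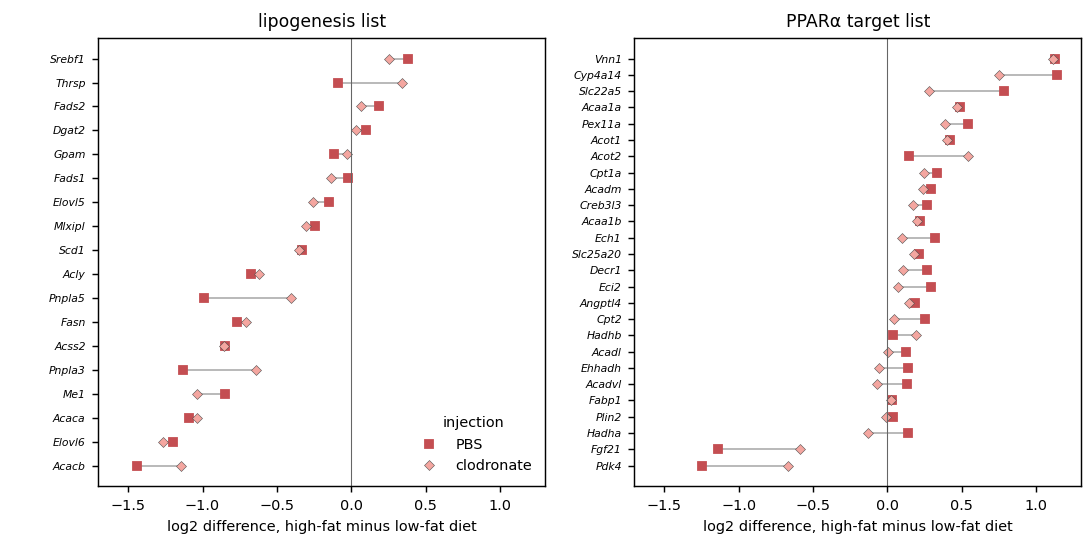
Log2 difference between high-fat and low-fat diet (horizontal axis) for the 18 detected lipogenesis genes and 26 detected PPARα targets (vertical axis), with 1 point per injection group and a line joining the pair. Most lipogenesis genes lie left of 0, down to -1.44 for Acacb with PBS, and most PPARα targets lie right of 0, up to 1.14 for Cyp4a14 with PBS, with Pdk4 and Fgf21 on the left.

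The diet differences in both injection groups overlapped in part. Of the 29 and 31 genes 2-fold or more higher, 10 were shared, where 0.104 would be shared by independent lists, and of the 29 and 64 lower genes 14 were shared, where 0.215 would be. Across genes Pearson's r was 0.347 and Spearman's rho 0.257.

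Averaged over both injections, the high-fat diet changed 146 genes in limma with Benjamini-Hochberg adjustment, of which 75 rose and 71 fell. With values below 4 taken as 4, 145 of the 146 differed in the same direction with both injections, all but Osbpl3. Of the 18 lipogenesis genes 10 fell and 0 rose, and adjusted over the list alone 12 fell and 1 rose. Elovl6 fell by 1.23 ± 0.05 (SD of the differences with the 2 injections, n = 2; limma, Benjamini-Hochberg adjusted p = 0.000161), Acaca by 1.07 ± 0.04 (limma, Benjamini-Hochberg adjusted p = 0.000499) and Fasn by 0.74 ± 0.04 (limma, Benjamini-Hochberg adjusted p = 0.00049). Scd1, stearoyl-CoA desaturase, fell by 0.34 ± 0.01 by the brightest probe set (limma, Benjamini-Hochberg adjusted p = 0.0101), and another Scd1 probe set differed by -0.84 with PBS and -0.87 with clodronate. Srebf1, a transcription factor of lipogenesis, did not pass and was higher by 0.32 ± 0.09 (limma, Benjamini-Hochberg adjusted p = 0.0975).

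Of the 26 PPARα targets 3 rose and 1 fell, and adjusted over the list alone 11 rose and 2 fell. Vnn1 rose by 1.12 ± 0.01 (limma, Benjamini-Hochberg adjusted p = 0.000161), Cyp4a14 by 0.94 ± 0.27 (limma, Benjamini-Hochberg adjusted p = 0.00101) and Pex11a, named as the remaining member that passed, by 0.46 ± 0.11 (limma, Benjamini-Hochberg adjusted p = 0.0321). Pdk4, which inhibits pyruvate dehydrogenase, fell by 0.96 ± 0.41 (limma, Benjamini-Hochberg adjusted p = 0.0481). Cpt1a did not pass, with a mean difference of 0.29, nor did Fgf21, which was lower by at least 1.14 (log2) with PBS and by at least 0.59 with clodronate. Ppara itself, not a member of the list, was higher by 0.31 with PBS and 0.33 with clodronate, and its other probe sets were higher too. Of the 10 lipid droplet and PPARγ genes 2 rose, Fitm1 by 1.27 ± 0.27 and Cd36 by 0.88 ± 0.21 (limma, Benjamini-Hochberg adjusted p = 0.00244 for each), and 4 rose adjusted over the list alone. Pparg was higher by 0.70 ± 0.16 without passing.

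In glucose metabolism, G6pc, glucose-6-phosphatase, fell by 0.91 ± 0.03 (limma, Benjamini-Hochberg adjusted p = 0.000294), Pklr, liver pyruvate kinase, by 0.85 ± 0.04 (limma, Benjamini-Hochberg adjusted p = 0.00125) and Igfbp1 by 1.12 ± 0.49 (limma, Benjamini-Hochberg adjusted p = 0.00407). These were 3 of 10 detected members, and 4 fell adjusted over the list alone. Of 18 cholesterol synthesis genes Msmo1 rose and Fdps and Pmvk fell, and adjusted over the list alone 3 rose and 4 fell. In the xenobiotic list Abcc3 and Cyp1a2 rose by 0.66 and 0.63, 2 of 10 members, and 3 rose and 1 fell adjusted over the list alone. Among sex-biased genes Cyp2b9 rose, and Cyp17a1 and Elovl3 fell by 0.99 and 0.55. Cxcl1, a neutrophil chemokine, and Saa1 rose by 0.91 each, as the single members called in the interleukin-1 and NF-κB list and in the acute phase list. In the Kupffer cell list 0 were called and 1 fell adjusted over the list alone.

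Clock genes rose and fell with the diet. Of 12 detected members Dbp, Per3, Tef and Ciart rose, and adjusted over the list alone 8 rose and 4 fell. Ciart was below 4 on both low-fat arrays and at 4.14 in the high-fat PBS pool, so that its call rests largely on values below 4. Arntl, among those that fell over the list alone, was at 4.32 in the low-fat PBS pool and below 4 in the other pools. Dbp rose by 1.32 ± 0.15 (limma, Benjamini-Hochberg adjusted p = 0.000161) and Tef by 0.83 ± 0.11 (limma, Benjamini-Hochberg adjusted p = 0.00761). Cry1, which did not pass over all genes, was lower by 0.83 ± 0.64. Outside the list, Cyp2b9, Usp2 and Tpm2 rose, and Lepr, Fabp5, Tff3, Acpp, Mpp4 and Steap2 fell. Osbpl3 and Aqp4 were called as well, but were at most at 4.02 and 4.54 on any array, and their rise rests on values below 4. Fabp5 fell by 2.27 ± 0.42 (limma, Benjamini-Hochberg adjusted p = 7.3e-05).

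The diet calls rested on the variance model. With eBayes without the mean-dependent prior, 0 rose and 0 fell at a smallest adjusted p of 0.182 (limma, Benjamini-Hochberg) and 894 genes had an unadjusted p under 0.05, against 1141 in the main model. No member of any list was called in that setting. Centring of each array gave 107 genes that rose and 58 that fell.

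**Figure D4:**
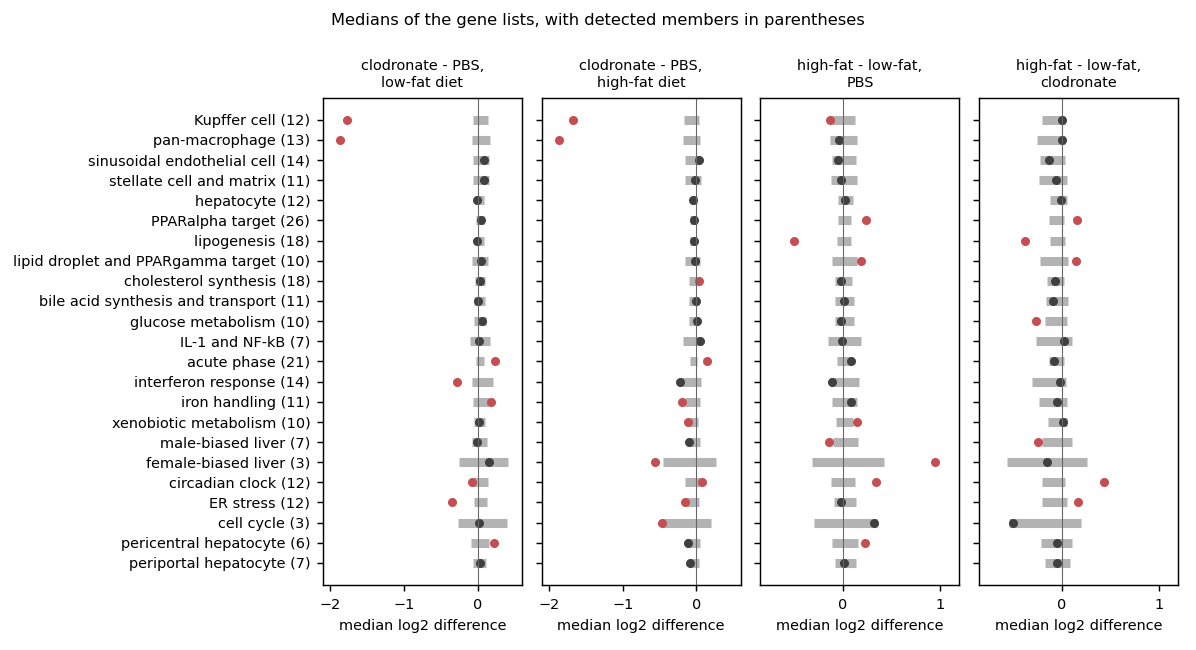
Median log2 difference (horizontal axes) of 23 gene lists (vertical axis) in the 4 pair comparisons, with grey bars for the central 95% of 10000 matched random lists and red points outside them. The macrophage lists lie far left after clodronate (-1.77 and -1.67 for Kupffer cell genes), lipogenesis lies left and PPARα targets right of the bars in both diet comparisons.

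The difference of the clodronate effect between the diets is given as a value without a test, for some of the genes taken by the fixed rule. Cish was higher after clodronate by 1.72 on the low-fat diet and lower by 0.78 on the high-fat diet, a difference of differences of -2.50. Socs2, Rgs3 and Serpina4-ps1 had values of -1.78, -1.59 and -1.63 in the same direction, but another Rgs3 probe set had -0.43. Lcn2 had a value of -2.06, with 6.89 already reached in the high-fat PBS pool. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a value of -1.36. C1qb and Orm2 had values of 1.87 and 1.81, and Pik3cd and Cd5l, below 4 in the low-fat clodronate pool, of at least 2.62 and 1.89. The Kupffer cell and pan-macrophage lists had medians of 0.14 and 0.08, at percentiles 99.6 and 98.1 of random lists. Members below 4 in both clodronate pools entered these medians only with the diet difference with PBS, its sign turned. Of 8650 genes 21 had values of 1 or more and 100 of -1 or less. After centring of each array the counts were 37 and 58, and after quantile normalization 52 and 46, so the size and direction of this imbalance rested on the scaling.

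Of the 32 lists computed, 23 had a percentile. They lay outside the central 95% of random lists in 8 cases for clodronate on the low-fat diet and 10 on the high-fat diet. For diet these were 9 with PBS and 7 with clodronate, and for the difference of the clodronate effect between the diets 8. Of lists of unrelated genes, 1.15 would lie outside. Genes of a list can vary together between single pools, so the excess is no measure of chance. Female-biased genes, with 3 detected, had medians of 0.95 with diet under PBS and -0.56 with clodronate on the high-fat diet, both outside, but of -0.15 with diet under clodronate and 0.15 with clodronate on the low-fat diet. Cyp17a1 was lower with diet under PBS, by 0.73, against the median. The values of 0.95 and -0.56 of this list share the high-fat PBS array and are not independent. Male-biased genes were lower with diet, at -0.14 and -0.24. Pericentral hepatocyte genes had medians of 0.22 with clodronate on the low-fat diet and 0.23 with diet under PBS, but of -0.11 with clodronate on the high-fat diet and -0.05 with diet under clodronate, a median difference of differences of -0.31. Of these pericentral values, 0.22 and 0.23 share the low-fat PBS array, and -0.11 and -0.05 the high-fat clodronate array. Periportal genes had medians between -0.08 and 0.03 in the 4 comparisons. Cell cycle genes, with 3 detected, had a median of -0.47 with clodronate on the high-fat diet. Bile acid genes had medians between -0.09 and 0.01 in the 4 comparisons with 0 of 11 called. Ctsc, a lysosomal protease in the periportal list, fell with clodronate by 0.44 ± 0.05 (limma, Benjamini-Hochberg adjusted p = 0.0257). Among the remaining cell types, monocyte, dendritic cell, B cell, cholangiocyte, red blood cell and adipocyte lists had 1 detected member each, neutrophils 2, and T cells and pancreatic acinar cells 0. Those of the monocyte and dendritic cell lists, Plac8 and Zbtb46, differed by 0.08 and 0.03 on the low-fat diet and by 0.05 and 0.15 on the high-fat diet after clodronate, whereas Ighm was higher by 0.66 and 1.01. The neutrophil genes S100a8 and S100a9 were at 4.15 and 4.05, just over the floor, in the low-fat clodronate pool and below 4 in the other pools, and both were called as higher adjusted over the list alone and not over all genes.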

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

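The values in this part drew attention because the clodronate effects on the diets had opposite signs. No explanation was tested, and the difference between the diets was not tested, since each diet had 1 array per injection.

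Atoh8, a transcription factor that responds to iron, was 2-fold or more apart in opposite directions, with a clodronate difference of 1.098 (log2) on the low-fat diet and -1.001 on the high-fat diet, from levels of 4.34 and 5.26 with PBS, close to the floor of 4. The 11 iron handling genes, which include Atoh8, had a median of 0.19 after clodronate on the low-fat diet, at percentile 99.0 of random lists, and -0.19 on the high-fat diet, at percentile 0.82. Id1, another member, differed by 0.75 and -0.22, while Hmox1 and Slc11a1 fell on both diets. The 12 circadian clock genes had a median of -0.0707 after clodronate on the low-fat diet, at percentile 2.34, and 0.0754 on the high-fat diet, at percentile 99.5. The latter turned negative with the mean over all probe sets. The clock medians are small beside those of the diet comparisons, 0.34 with PBS and 0.44 with clodronate.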

How the results depend on the processing

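Macrophage genes stayed lower after clodronate under each alternative run. The Kupffer cell median ranged from -3.35 to -1.74 on the low-fat and from -2.31 to -1.59 on the high-fat diet, and the lipogenesis median with diet from -0.52 to -0.24 with PBS and from -0.48 to -0.31 with clodronate. The test with values below 4 set to 4 before the fit was chosen after seeing the data; the other alternatives were planned.

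Of 423 differences of single genes recomputed, 287 stayed within the tolerance, 136 moved and 0 reversed. Of 206 averaged effects of genes, 154 kept their side of the threshold and 52 no longer passed. Of 182 list medians, 142 stayed, 39 moved and 1 reversed. Of 148 counts, 71 stayed within 1.5 times. Except where the setting itself acts on the count (fold threshold, floor, number of genes tested), the cause was not tested.

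At 1.5-fold, clodronate counts were 151 higher and 141 lower on the low-fat diet, 55 and 258 on the high-fat diet, and 5 and 80 on both. Diet counts were 186 and 127 with PBS, 146 and 414 with clodronate, and 48 and 53 in both. The difference of differences gave 159 and 625. At 3-fold, the counts in this order were 3 and 35, 2 and 37, 0 and 32, 5 and 4, 7 and 12, 3 and 2, and 4 and 13.

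With no floor and no filter, 30 genes were higher and 110 lower after clodronate on the low-fat diet, 17 and 112 on the high-fat diet, and 2 and 80 on both. Diet with clodronate gave 47 higher, and the difference of differences 80 and 156. In limma 1 gene rose with clodronate, and 19 rose and 23 fell with diet. Kupffer cell medians were -3.35 and -2.31, and the lipogenesis median with clodronate was -0.48. With a floor of 3, 13 genes were higher after clodronate on the high-fat diet and 38 had a positive difference of differences. Kupffer cell medians were -2.59 and -1.96, and the lipogenesis median with clodronate was -0.48. With a floor of 5, 12 genes were higher after clodronate on the low-fat diet, 4 higher and 43 lower on the high-fat diet, 15 lower with diet under PBS and 8 lower with diet in both injections. The difference of differences gave 8 and 63, the Kupffer cell median on the high-fat diet was -1.77 and the lipogenesis median with PBS -0.24.

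With the mean over all probe sets, 3 genes were higher after clodronate on the high-fat diet, 14 lower with diet under PBS, 20 higher and 34 lower with diet under clodronate, and 5 lower in both. The difference of differences gave 7 and 50. In limma 2 genes rose with clodronate, and 26 rose and 26 fell with diet. The circadian clock median after clodronate on the high-fat diet reversed to -0.0287.

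After centring of each array, 41 genes were lower with diet under clodronate, the difference of differences gave 37 and 58, and the PPARα target median with diet under clodronate was 0.26. After quantile normalization the counts were 40, and 52 and 46, and 6 genes rose with clodronate in limma.

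In limma without the mean-dependent prior, 0 genes rose and 39 fell with clodronate, all 39 among the 94, and 0 rose and 0 fell with diet. With genes at 6 or more only, 16 rose with clodronate, and 162 rose and 139 fell with diet, of which 128 were among the 146. With values below 4 set to 4 first, 1 rose and 53 fell with clodronate, and 29 rose and 31 fell with diet, all 54 and 60 among the main calls. Signal over background limits the dim genes, since 42 of 94 clodronate calls and 18 of 146 diet calls had an array below 4.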

Other observations

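Of the tests below, those of array scaling, hour of collection, cells left in place and single probe sets were chosen after the result was seen. The test of further growth hormone targets was fixed before their difference of differences was looked at, when the averaged diet effect of Bcl6 had been seen.

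Cd74, the invariant chain, and H2-Aa, H2-Ab1 and H2-Eb1, chains of MHC class II, fell after clodronate in limma with Benjamini-Hochberg adjustment. They were chosen after their values were seen, and antigen presentation genes were not tested as a group. Cd74 differed by -1.52 on the low-fat diet and -1.87 on the high-fat diet, and H2-Aa by -1.49 and -1.34. Lpl, lipoprotein lipase, also chosen after its values were seen, fell after clodronate, with differences of -1.40 and -2.18, and fell with the high-fat diet, with differences of -0.85 with PBS and -1.63 with clodronate. It is a gene of macrophages as well as of fat tissue.

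Clock genes differed between the diets by phase. Over 8 detected genes that peak with Dbp, the median diet difference, averaged over the injections, was 0.72, and over 4 that peak with Arntl it was -0.44. Arntl itself was above 4 only in the low-fat PBS pool, so its diet difference with clodronate entered as 0. The gap of 1.16 lay beyond the upper end of the central 95% of matched random lists, 0.23. The groups were compared after the diet differences of clock genes had been seen, so the random lists are no independent check of the gap. The parts of the gap had opposite signs, which argues against array-wide scaling. An hour of tissue collection that differed between diets could give the same picture, and so could an effect of the diet on the clock. The gaps in the injection groups were 1.21 with PBS and 1.31 with clodronate, of the same sign, so hour and diet cannot be told apart, because the labels give no hour per group.

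Growth hormone responsive genes such as Cish, Socs2, Onecut1, Rgs3 and Serpina4-ps1 were highest in the low-fat clodronate pool and lowest in the high-fat clodronate pool. With Susd4, which was highest in the same pool but lowest in the low-fat PBS pool, these 6 genes were picked after their values were seen. The 200 neighbours in expression of each gene, which were not picked, had median differences of differences no lower than -0.164, against values from -2.50 for Cish to -1.59 for Rgs3 in 5 of the 6, which argues against scaling at that expression level as the whole cause for these. Susd4, at -0.41, lay within the range of its neighbours. A Rgs3 probe set other than the one used had a value of only -0.43. Further targets of growth hormone had a median of -0.41, with the repressed gene Bcl6 turned, at percentile 0.11 of random lists. Gadd45g and Igfals had -1.01 and -0.57, Igf1 -0.25, and Bcl6 was close to 0. Unequal growth hormone signalling at collection may thus be a hypothesis for part of this pattern, and since growth hormone is released in pulses, collection and treatment stay open as its origin.

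Some macrophage transcripts were left in the high-fat clodronate pool. C1qb kept 6.504% and Cd5l 3.55% of their PBS level there, against 1.77% and at most 0.955% on the low-fat diet, while Clec4f, Vsig4 and C1qa kept at most 2.33%, 1.97% and 2.58%. Csf1r kept 5.82% there and 4.92% on the low-fat diet by the probe set used. Another Csf1r probe set was higher by 1.05 in the high-fat clodronate pool, so that this gene leaves the question open. Between the clodronate pools, with values below 4 taken as 4, the Kupffer cell and pan-macrophage lists each had a median difference of 0. Of the Kupffer cell markers 2 were higher on the high-fat diet and 3 lower. For the pan-macrophage markers these counts were 3 and 5, so C1qb and Cd5l do not stand for their lists. Signal of a single probe set is argued against, since the other C1qb probe sets were higher in the high-fat than in the low-fat clodronate pool by at least 1.097. Equal survival of Kupffer cells could not be excluded. Among the 9 genes taken, the highest measured share was 3.30 times the lowest bound with values below 4 taken as 4. With values below 5 taken as 5, it was 1.83 times the lowest share. These ratios rest on the C1qb probe set used, which differed by -3.94 (log2) after clodronate on the high-fat diet. Other C1qb probe sets differed by -4.33 and -3.33, so the ratios change with the probe set. Newly arrived macrophages poor in Clec4f may be another source, which was not tested.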
